A study of Komagataella phaffii with 32 samples.

How the data were processed

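RNA was sequenced from Komagataella phaffii (also called Pichia pastoris) cultures of 3 strains: the wild type (WT, X-33), a crz1 mutant (PJA-001) and a rim101 mutant (PJA-007). Cells grew in rich medium with glycerol at 20 g/L and 28 °C, were diluted to an OD600 of 0.2 and grown to about 0.6, then resuspended in medium buffered with 50 mM TAPS. Time 0 (T0) was taken at pH 5.5, and 15, 30 and 60 min (T15, T30, T60) were taken at pH 8.0. WT and crz1 have 3 libraries at each time and rim101 has 2, which makes 32 libraries in 12 groups. No library at pH 5.5 was taken at 15, 30 or 60 min, so each later time differs from T0 in pH, in time after resuspension and in growth together. The series text names GS115 where the labels of the samples name X-33. The replicates are separate libraries per the labels, and the limma p-values of genes weigh changes against the spread between them, pooled over all groups. The p-values of the list tests, the permutation and the Fisher exact test answer other questions.

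The deposited table of expression holds RPKM (reads per kilobase of gene, scaled to a fixed number of mapped reads) on the linear scale for 5040 genes, computed by the authors. The submitters' processing notes name Bowtie2 and edgeR with no version, and the genome build is not given in the sources used here. Libraries were made from poly-A RNA and were not directional, so reads from overlapping genes on opposite strands cannot be told apart. Of the genes named in the report, GTT1 is the only one whose span overlaps another gene. Of the gene spans, 92.2% are a multiple of 3 bases long, so the length in the unit is close to the coding length. All 5040 identifiers matched the reference table of locus tags, with equal coordinates. A second file, the authors' deposited table of comparisons, gives for 4581 genes an unadjusted p value, an adjusted p value (FDR, a p value whose method of adjustment is not stated) and a log2 fold change of each group over WT T0. Its log2 fold changes and p values were set beside the results here and entered no test.

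No count table was used here. The depth of each library was read from the spacing of its values: low RPKM multiplied by gene length fall on whole multiples of a step, and the size of the step gives the number of reads behind the unit. Between 93.9% and 97.1% of genes with low values lay within 0.1 of a whole read. In 2 libraries (WT T15 replicate 2 and rim101 T30 replicate 1) there were 2 step sizes, and their depths were summed. Since the unit is already divided by depth, no count model was run.

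Values were tested as log2(RPKM + 1), which understates changes of genes near 1 RPKM. Genes with a mean under 1 RPKM over all libraries were left out, leaving 4226. limma 3.58.1 (R 4.3.3) fitted all 12 groups at once with an intensity trend (limma-trend, 20 residual degrees of freedom, two-sided moderated limma test). P-values were adjusted by the Benjamini-Hochberg method over the genes tested within each comparison. A gene rose or fell at an adjusted p under 0.05. The count given first for each comparison also asks for a change of at least 2-fold. With 2 rim101 libraries per group, the test of this strain leans on the spread pooled over all groups. Comparisons were each later time against T0 in each strain, each mutant against WT at each time, the difference in response (mutant change since T0 minus WT change since T0) and the difference in response between the mutants. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for checks and plots.

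The comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names RIM101 and CRZ1 in every comparison, the 6 largest rises and 4 largest falls of WT at each time, and the 6 most negative and 4 most positive differences in response of each mutant. At T0 it names the 4 most positive and 4 most negative differences of each mutant from WT. It asks for an adjusted p under 0.05, at least 2-fold, a mean of at least 10 RPKM, the same direction in every library, and a symbol or description. It also names up to 4 members of each list with the largest WT change and up to 3 per mutant with the largest difference in response. The same rule was extended to the direct comparisons of mutants with WT at pH 8.0 after the data were seen. Genes named outside the rule are marked as chosen after their values were seen. No fold is given for a gene whose reference group is listed at 0 in every library.

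In all, 27 lists of genes were written from Saccharomyces cerevisiae and K. phaffii names and matched exactly to the symbols in the file: phosphate acquisition and storage, iron, copper and zinc uptake, monovalent cation and proton transport, calcium handling and calcineurin signalling, the Rim alkaline pH pathway, cell wall biogenesis, glycolysis, gluconeogenesis and glyoxylate cycle, tricarboxylic acid cycle, respiratory chain, glycerol metabolism, methanol utilisation and peroxisome, trehalose and glycogen, oxidative stress defence, molecular chaperones, cytosolic ribosomal proteins, ribosome biogenesis, mitochondrial ribosome, amino acid biosynthesis, sulfur assimilation, ergosterol biosynthesis, hexose transport, nitrogen source and amino acid transport, vacuolar ATPase, proteasome, cell cycle and histones, and mating and sporulation as markers of another cell state. Numbered copies such as PHO84-1 match no list name exactly and are described singly. A match by symbol was not checked against the description in the file, which names another function for some members (FEP1 and TRM1 for example). Members are counted at an adjusted p under 0.05 with no minimum fold. The 26 lists with at least 5 measured members were tested with camera (preset correlation 0.01), adjusted over lists within each of 11 comparisons, and again with camera with an estimated correlation and with fry. camera compares a list with all other genes. The directional p of fry tests whether the members move one way on balance, its mixed p whether they change in either direction, and neither compares the list with other genes.

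Alternatives were 2 other scalings (median-ratio factors and quantile normalization), pseudocounts of 0.1 and 5 RPKM, a minimum mean of 10 RPKM or none, no minimum fold, a fit of the compared groups alone, array weights, replicate number as a block and leaving out each library in turn. Added after seeing the data were the share of reads in the 5 top genes as a covariate, library type (defined in the report) as a covariate, leaving out the libraries with the higher median, leaving out genes listed at 0 in a compared library, and lists with numbered copies included. Same-numbered libraries were checked for pairing by the correlation of their deviations from the group means. In 3 of 10 comparisons with 3 such pairs every correlation was over 0.1: crz1 T15 vs T0 (0.256 to 0.565), crz1 vs WT at T0 (0.286 to 0.441) and crz1 vs WT at T30 (0.454 to 0.903). In crz1 vs WT at T15 all 3 were negative (-0.638 to -0.241). How often such values arise by chance was not computed. The numbers may therefore pair libraries in the 3 comparisons over 0.1, which the labels do not state. Because 1 library per group remains in rim101 when its other library is left out, that library is assumed to vary like the other groups. The procedure was tested on simulated data with 200 changed genes in 10 draws. With independent spread it recovered 24.3% of 2-fold and 61.5% of 4-fold changes in WT T30 vs T0, and 4.63% and 32.7% in the rim101 minus WT difference in response at T30, with a median of 2.5 and 1.5 wrong calls. When a component shared by all genes of a library was added to the simulation, single draws gave up to 1844 wrong calls in WT T30 vs T0, 2148 in rim101 vs WT at T30 and 2113 in the crz1 minus WT difference in response at T30.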

Results

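Expression was measured by RNA sequencing in 32 libraries of K. phaffii, from WT and from mutants of the calcineurin-regulated transcription factor Crz1 and of the alkaline pH transcription factor Rim101. WT and crz1 had n = 3 libraries and rim101 n = 2 at each of 0, 15, 30 and 60 min, with pH 5.5 at T0 and pH 8.0 afterwards. The series asks how each factor shapes the response to alkaline pH. The depth read from the spacing of the values was between 4.95 and 19.8 M reads per library, with a median of 8.42 M. In each library between 837 and 1423 of the 5040 genes were listed at exactly 0, and 458 were at 0 in all 32. Pearson correlations of replicate pairs on the log2 scale, across genes, ran from 0.843 to 0.990, and no replicate pair shared an identical nonzero value. Replicate pairs differed by at least 20.5 times what read counting alone would give (chi-square per degree of freedom), so counting error is a small part of the spread.

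The libraries fell into 2 types that partly follow the groups. In 9 libraries the median of the tested genes was between 46.6 and 56.6 RPKM, against 21.01 to 35.4 RPKM in the other 23. In the same 9 libraries the 5 most abundant genes (SPI1, TDH3, TEF2, PAS_chr1-1_0479 and PAS_chr2-1_0812) took 5.48% to 7.48% of gene reads, against 9.35% to 17.01%. The 9 were WT T30 replicate 1, WT T60 replicates 1 and 2, replicate 1 of crz1 at T15, T30 and T60, rim101 T15 replicate 2 and both rim101 T30 libraries. None was at T0, so adjusting for type may remove part of the response. Many counts of changed genes therefore stand below with the values that 1 or both of 2 other scalings give. The median log2 change of all tested genes against T0 was 0.17, 0.62 and 0.65 at T15, T30 and T60 in WT, 0.24, 0.43 and 0.29 in crz1 and 0.41, 0.85 and 0.13 in rim101. List medians below are given relative to this shift where so stated. Over all 4226 tested genes, 566, 1020 and 1136 rose and 219, 172 and 195 fell in WT at T15, T30 and T60 with no minimum fold. Counts of list members below are to be read beside these.

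**Figure D1:**
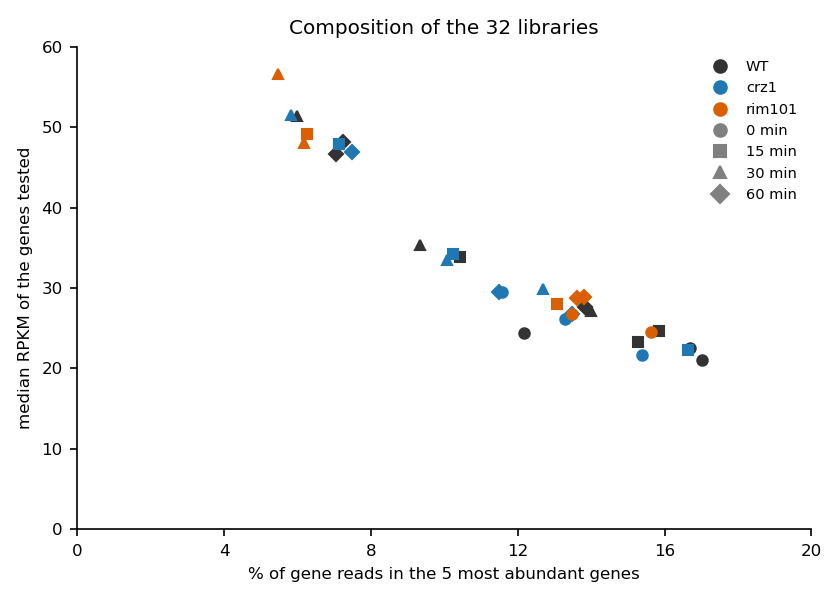
Each point is 1 of the 32 libraries, with the percent of gene reads in the 5 most abundant genes on the x axis and the median RPKM of the 4226 tested genes on the y axis. The 9 libraries with a median of at least 46.6 RPKM all lie at 7.48% or less.

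RIM101 itself (PAS_chr3_0625, chromosome 3, 1185885 to 1187711) rose in WT from 36.3 ± 13.8 RPKM at T0 to 128 ± 24.5 at T15, 133 ± 11.4 at T30 and 126 ± 9.99 at T60 (SD, n = 3). These were log2 changes of 1.85 (SE 0.23, adjusted p = 4.71e-06), 1.92 and 1.84. In crz1 it also rose, by 1.10 (adjusted p = 0.00106), 1.34 (0.000184) and 1.24 (0.000617). In rim101 its mRNA was 28.7 ± 3.85, 30.4 ± 3.77, 33.2 ± 12.6 and 27.0 ± 3.23 RPKM (SD, n = 2) and did not pass at any time, with log2 changes of 0.08, 0.16 and -0.08. Against WT, RIM101 mRNA in rim101 was lower at T15, T30 and T60 by log2 differences of -2.02 (adjusted p = 1.76e-05), -2.01 (1.25e-05) and -2.18 (6.06e-06). CRZ1 mRNA was not lower in crz1, at 28.8, 27.8, 38.4 and 39.3 RPKM, with log2 differences from WT of 0.49, 0.30, 0.34 and 0.24, none of which passed. CRZ1 (PAS_chr2-2_0202, chromosome 2, 2007954 to 2009510) was at 20.1, 21.9, 28.9 and 32.7 RPKM in WT, and its log2 change of 0.69 at T60 (adjusted p = 0.0394) turned to -0.13 with quantile normalization and lost its call without WT T60 replicate 1 (adjusted p = 0.123), WT T60 replicate 2, WT T0 replicate 1 or WT T0 replicate 2. Since mRNA of a mutated gene can still be made, these levels do not check either genotype.

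In WT, the 6 largest rises named at 15 min of pH 8.0 were those of a regulatory protein, 2 metal transporters and 3 other genes. MIT1 (PAS_chr3_0251), described in the file as a cAMP-independent regulatory protein, went from 1.06 ± 1.83 to 268 ± 18.9 RPKM (SD, n = 3), a log2 change of 7.38 (SE 0.54, adjusted p = 1.85e-09). The zinc transporter ZRT1 (PAS_chr3_0516) rose by 5.62 (SE 0.80, adjusted p = 2.01e-05) and the siderophore transporter SIT1-1 (PAS_chr3_0662) by 4.96 (SE 0.49, adjusted p = 1.24e-07). MET1 was listed at 0 at T0 and reached 39.7 ± 8.89 RPKM, PAS_chr4_0588 was listed at 0 and reached 34.8 ± 6.98 RPKM, and PAS_chr1-3_0016 rose by 4.88 (SE 0.70). FEP1 fell from 84.2 ± 25.8 RPKM to a listed 0 in all 3 libraries (adjusted p = 2.87e-09), TMA10 from 77.1 ± 76.8 RPKM to a listed 0 (adjusted p = 9.5e-06), the disaggregase HSP104 by log2 changes of -5.59 (SE 0.77) and the glutamate dehydrogenase GDH3 by -5.56 (SE 0.38, adjusted p = 5.9e-10). These genes moved the same way in every library. In limma, 427 genes rose and 149 fell at least 2-fold, and 785 changed with no minimum fold. The counts were 369 and 231 with quantile normalization, and 199 of the 576 genes were listed at 0 in at least 1 compared library.

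At 30 min MIT1 (log2 change 6.46), ZRT1 (5.48), SIT1-1 (5.16) and PAS_chr4_0588 stayed among the largest rises of WT. They were joined by ZPS1 (PAS_chr3_0517), which lies next to ZRT1 and rose by 5.38 (SE 0.70, adjusted p = 5.39e-06), and by MSC1, which rose by 5.15 (SE 0.65, adjusted p = 4.29e-06). The phosphate transporter copy PHO84-2 (PAS_chr3_0141) fell from 160 ± 39.0 RPKM to a listed 0 in all 3 libraries (adjusted p = 3.44e-13), as did FEP1 and TMA10. PCK1, of gluconeogenesis, fell by log2 changes of -5.31 (SE 1.43, adjusted p = 0.00783), a call lost without WT T30 replicate 1 (adjusted p = 0.0882) or WT T0 replicate 1, and without all higher-median libraries. In limma 726 genes rose and 115 fell at least 2-fold, against 460 and 245 with median-ratio scaling and 284 and 212 with quantile normalization. The total of 841 genes was 509 without WT T30 replicate 1, which is of the higher-median type.

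By 60 min in WT, MIT1 (6.12) and SIT1-1 (4.77) were still among the largest rises, and PHO84-2, FEP1 (log2 change -5.64), TMA10 and the fumarate reductase OSM1 (-4.51, SE 0.66, adjusted p = 3.99e-05) among the largest falls. HAC1, the transcription factor of the unfolded protein response, rose by 4.74 (adjusted p = 0.00105), ECM1 by 4.64 (adjusted p = 0.00285) and PAS_chr2-1_0727 by 4.54. RRP14 also passed, but not without WT T60 replicate 1 (adjusted p = 0.203), WT T60 replicate 2 or any of the 3 WT T0 libraries. In limma 826 genes rose and 141 fell at least 2-fold, 427 and 283 with median-ratio scaling and 266 and 267 with quantile normalization. The total of 967 was 641 without WT T0 replicate 3, 463 without WT T60 replicate 1, 552 without WT T60 replicate 2 and 1681 without WT T60 replicate 3. Without the 9 higher-median libraries 1 WT T60 library remains, so no count or call is given.

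Among the phosphate genes on the list more rose than fell in WT at each time, while metal uptake genes changed both ways. The lists leave out numbered copies. Of these, PHO84-2 fell to a listed 0 at T30 and PHO84-1 changed by -4.02 at T60, while the siderophore transporter SIT1-1 rose. Of 12 measured phosphate genes, 7, 8 and 7 rose and 1 fell at T15, T30 and T60 (8, 9 and 7 rose and 1 fell when adjusted over the list alone). With quantile normalization 7, 7 and 5 rose and 0 fell. The sodium-phosphate symporter PHO89 (PAS_chr2-1_0235, chromosome 2, 442707 to 444437) went from 185 ± 103 RPKM to 3732 ± 125, 4178 ± 753 and 2442 ± 752 RPKM (SD, n = 3), a log2 change of 4.69 (SE 0.47, adjusted p = 1.27e-07) at T30. PHO81, a regulator of the phosphate pathway, rose by 3.59 (SE 0.47) and the polyphosphate synthesis genes VTC2 and VTC4 by 3.10 (SE 0.30) and 2.60 at T30. The list was higher than other genes by camera (adjusted p = 0.000594, 0.0002 and 0.0379, against an adjusted p = 0.246, 0.175 and 0.784 with an estimated correlation). Of 23 genes of iron, copper and zinc uptake 8, 10 and 8 rose and 2, 4 and 3 fell (10, 10 and 10 rose and 6, 4 and 3 fell when adjusted over the list alone), with ZRT1 and the reductase FRE1 (4.05 at T60, SE 0.70) rising and FEP1 falling. At T60 both scalings gave as many of these members falling as rising (5 and 5, 3 and 3), and camera called none of the 3 times. Among 8 monovalent cation and proton transport genes 2, 5 and 5 rose and 0, 1 and 1 fell (2, 6 and 5 rose and 1, 2 and 1 fell when adjusted over the list alone). Median-ratio scaling gave 3 rising and 2 falling at T30 and at T60, and quantile normalization 3 and 1, then 1 and 1. The sodium pump ENA2 went from 38.5 ± 4.19 to 279 ± 78.3 RPKM at T30 (log2 change 2.80, SE 0.24, adjusted p = 1.7e-08), and the potassium transporter TRK2 rose by 3.53 (SE 0.56).

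Calcium genes and cell wall genes rose in part. Of 10 genes of calcium handling, 3, 5 and 5 rose and 0 fell (3, 6 and 5 adjusted over the list alone), led by the vacuolar calcium pump PMC1 (PAS_chr1-1_0117), which went from 12.3 ± 1.90 RPKM to 67.8 ± 7.06 at T15 and 71.3 ± 2.42 at T30 (SD, n = 3; log2 change 2.45, SE 0.28, adjusted p = 9.38e-07 at T30). With median-ratio scaling 2, 1 and 0 of the 10 rose. At T60 the median log2 change of the calcium list (0.47) lay below that of all genes (0.65). Of 28 cell wall genes 10, 14 and 12 rose and 0, 0 and 1 fell (11, 18 and 14 rose and 0, 1 and 1 fell when adjusted over the list alone), among them TIP1 (3.30 at T30, SE 0.52, adjusted p = 6.6e-05). With median-ratio scaling 8, 8 and 6 rose. At T60 the cell wall median as deposited (0.51) also lay below that of all genes. camera called the cell wall list at T15 and T30 (adjusted p = 0.0043 and 0.00976, but an adjusted p = 0.246 and 0.175 with an estimated correlation). Of 12 genes of the Rim pathway 1, 2 and 3 rose and 1, 0 and 1 fell (1, 1 and 3 rose and 1, 0 and 1 fell when adjusted over the list alone). At T30 both other scalings gave 1 rising and 1 falling, and at T60 1 and 1 (median-ratio) and 2 and 2 (quantile). RIM101 was the member that rose at all 3 times, and the repressor NRG1 fell at T15 by log2 changes of -2.60 (adjusted p = 0.0196), a call lost without WT T15 replicate 3 (adjusted p = 0.0881) or WT T0 replicate 1 and with quantile normalization (0.0615).

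Glycolysis genes fell in WT, and other lists of carbon metabolism changed in fewer members or both ways. Of 15 glycolysis genes 10, 13 and 14 fell and 0 rose (11, 14 and 14 fell when adjusted over the list alone), and the list median lay at -1.29, -2.15 and -2.20 relative to all genes. Glucokinase GLK1 fell by log2 changes of -2.49 (SE 0.33, adjusted p = 1.04e-05) at T60, pyruvate decarboxylase PDC1 by -2.90 (SE 0.47) and PFK1 by -1.87. camera put the list lower than other genes (adjusted p = 7.6e-12, 2.2e-21 and 1.85e-20, against an adjusted p = 0.246, 0.0633 and 0.0757 with an estimated correlation). Of 19 genes of the tricarboxylic acid cycle 8, 7 and 4 fell and 1, 0 and 2 rose (9, 8 and 4 fell when adjusted over the list alone), among them SDH1 (-2.75 at T30, SE 0.33, adjusted p = 1.77e-06) and ACO1 (-2.18 at T30). With median-ratio scaling 7, 12 and 7 fell. The camera adjusted p was 7.04e-06, 2.74e-10 and 0.00964, and the adjusted p = 0.246, 0.107 and 0.784 with an estimated correlation. Of 66 genes of the respiratory chain and ATP synthase 3, 18 and 10 fell and 2, 2 and 3 rose (3, 18 and 10 fell when adjusted over the list alone). Falling members were 9, 29 and 27 with median-ratio scaling and 4, 22 and 19 with quantile normalization. They were led by cytochrome c, CYC1, from 4386 ± 547 to 1023 ± 53.4 RPKM at T30 (log2 change -2.09, SE 0.19). Here camera gave an adjusted p = 0.00129, 1.49e-11 and 5.6e-06, and an adjusted p = 0.707, 0.251 and 0.784 with an estimated correlation. Among 17 genes of gluconeogenesis and the glyoxylate cycle 3, 2 and 1 fell and 2, 2 and 1 rose (3, 2 and 0 fell and 2, 2 and 1 rose when adjusted over the list alone), with FBP1 falling by -3.28 and PYC2 rising by 2.02 at T15. Median-ratio scaling gave 0 rising and 4 falling at T30 and 0 and 3 at T60, and quantile normalization 1 and 2, then 0 and 2. Its camera call at T30 (adjusted p = 0.00566) had an adjusted p = 0.592 with an estimated correlation. Of 6 glycerol genes GPD1 alone fell at T15 (log2 change -1.91), with a camera call at T30 (adjusted p = 0.0441, against an adjusted p = 0.572 with an estimated correlation).

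Ribosome biogenesis was the list with the most rising members in WT. Of its 102 genes 66, 80 and 75 rose and 0 fell (83, 87 and 87 rose when adjusted over the list alone), with NOP4 rising by 4.43 at T30 and NOC4 by 4.32 at T60. The list median lay 1.85, 1.48 and 1.34 above that of all genes. Fewer members rose at T30 and T60 with median-ratio scaling (62 and 53) and quantile normalization (50 and 42). camera gave an adjusted p = 2.97e-20, 3.52e-11 and 3.94e-09, and an adjusted p = 0.455, 0.608 and 0.804 with an estimated correlation. Among 75 cytosolic ribosomal protein genes, 0 rose and 0 fell in limma at any of the 3 times. With median-ratio scaling 5 fell at T60. camera put them below other genes at T30 and T60 (adjusted p = 0.00106 and 5.6e-06, against an adjusted p = 0.657 and 0.784 with an estimated correlation), and their median relative to all genes turned from -0.54 to 0.09 at T30 with quantile normalization. Of 58 genes of the mitochondrial ribosome 2, 1 and 0 rose and 0, 1 and 1 fell (0, 1 and 0 rose and 0, 0 and 1 fell when adjusted over the list alone), with MRP8 rising by 2.23 at T30. At T60 10 of them fell with median-ratio scaling and 5 with quantile normalization.

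More chaperone genes fell than rose at 15 min in WT, and more rose than fell at 60 min. Of 28 members 13 fell and 2 rose at T15, 5 fell and 4 rose at T30, and 1 fell and 15 rose at T60 (14 and 3, 5 and 4, 1 and 16 when adjusted over the list alone). The Hsp70 gene SSA3 went from 1096 ± 769 RPKM at T0 to 22.6 ± 10.2 at T15 and 1201 ± 90.4 at T60 (SD, n = 3), a log2 change of -5.38 (SE 0.63, adjusted p = 1.88e-06) at T15, and HSP78 fell by -4.85. HSP12 rose instead, from 371 ± 131 to 4184 ± 715 RPKM at T15 (log2 change 3.88, SE 0.35, at T30). The camera adjusted p was 2.8e-08 (lower), 0.0403 (lower) and 0.0592, and the adjusted p = 0.246, 0.657 and 0.834 with an estimated correlation. In oxidative stress defence 4, 9 and 9 of 25 rose and 1 fell (4, 12 and 11 rose when adjusted over the list alone), such as GTT1 (2.69 at T30) and AHP1 (1.81 at T30). With median-ratio scaling 5, 5 and 3 of them rose and 5, 4 and 2 fell, and with quantile normalization 6, 7 and 4 rose and 1, 3 and 2 fell. For GTT1, reads of an overlapping gene cannot be told apart. In trehalose and glycogen metabolism 2, 2 and 1 of 10 rose and 2, 2 and 3 fell (2, 2 and 1 rose and 3, 2 and 3 fell when adjusted over the list alone), with GDB1 up by 3.31 at T30 and GLG1 at -2.76 at T15. In methanol utilisation and peroxisome 4, 3 and 4 of 23 rose and 1, 0 and 0 fell (4, 2 and 4 rose when adjusted over the list alone), including PEX5 (3.36 at T15) and catalase CTA1 (2.34 at T15). The call of PEX5 was lost in each of the 6 fits with 1 library left out (highest adjusted p = 0.142 in limma, without WT T15 replicate 2). MIT1 and TRM1 (2.90 at T30) are among the rises at all 3 times. They are in this list by symbol alone, because the file describes TRM1 as a tRNA methyltransferase and gives no methanol role for MIT1.

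Sulfur genes rose in part, and amino acid genes rose less than all genes by median at T30 and T60. Of 24 genes of sulfur assimilation and methionine synthesis 9, 12 and 6 rose and 0 fell (10, 15 and 6 when adjusted over the list alone), among them the sulfate permease SUL1 (4.03 at T30), MET10 (2.78) and MET5 (2.44). camera called the list at T15 and T30 (adjusted p = 0.00909 and 0.0224, but an adjusted p = 0.697 and 0.657 with an estimated correlation), and at T60 the direction turned with scaling, with 1 rising and 5 falling under median-ratio factors and 1 and 4 under quantile normalization. Of 54 amino acid biosynthesis genes 12, 19 and 15 rose and 2, 3 and 5 fell (13, 21 and 15 rose and 4, 3 and 5 fell when adjusted over the list alone), with CPA1 at 2.35 at T15 and LEU1 at -3.04 at T30. With median-ratio scaling more of them fell than rose at T30 (7 and 5) and T60 (12 and 5). Their median log2 change as deposited lay below that of all genes at T30 (0.44 against 0.62) and T60 (0.34 against 0.65).

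**Figure D2:**
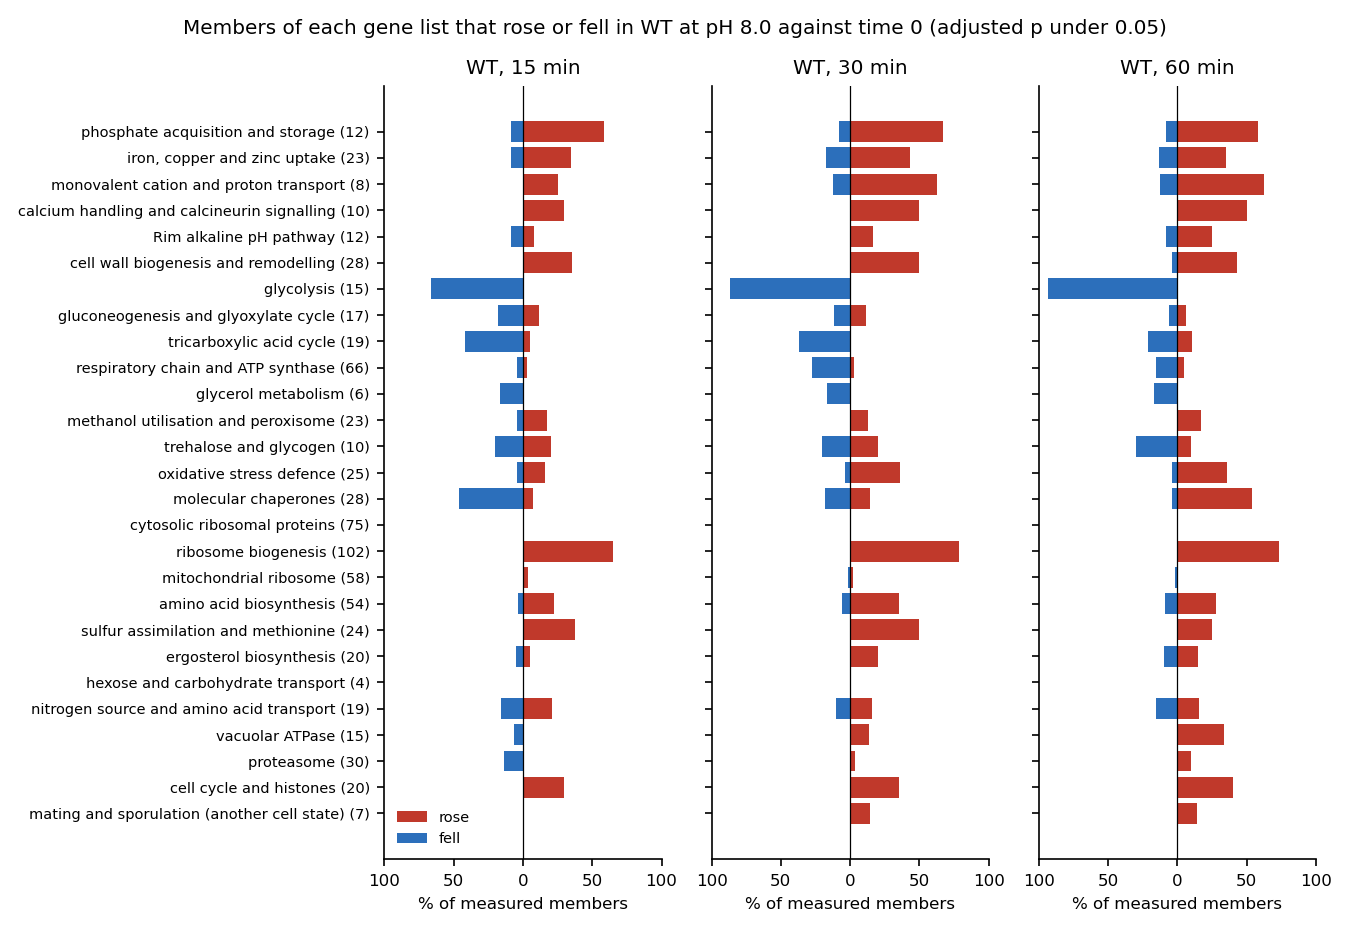
Bars give the percent of each list's measured members that rose (red) or fell (blue) in WT at T15, T30 and T60 against T0 at an adjusted p under 0.05 in limma, as deposited. Glycolysis has 10, 13 and 14 of 15 members falling and ribosome biogenesis 66, 80 and 75 of 102 rising, while at T60 the metal uptake and sulfur lists change direction or balance with scaling.

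The crz1 strain asks which part of the response needs Crz1, and at T0 it differed from WT in 3 genes. TOH1 (PAS_chr2-2_0271) was at 21.1 ± 4.43 RPKM in crz1 and 134 ± 28.8 in WT (SD, n = 3), a log2 difference of -2.60 (SE 0.23, adjusted p = 2.86e-07). The methionine sulfoxide reductase MXR2-1 (PAS_chr2-1_0008) was lower by -1.44 (SE 0.24, adjusted p = 0.00836), and the iron transporter FET4-1 (PAS_chr2-2_0009) was higher by 2.08 (SE 0.39, adjusted p = 0.0304). The call of MXR2-1 was lost without WT T0 replicate 2 (adjusted p = 0.157) or crz1 T0 replicate 1 or 2, with median-ratio scaling (0.276) and with quantile normalization (0.305). The call of FET4-1 was lost without WT T0 replicate 3 (adjusted p = 0.234), WT T0 replicate 2 or any crz1 T0 library, and with quantile normalization (0.175). In limma 1 gene was higher and 2 lower at least 2-fold, 308 had an unadjusted p under 0.05, and the 3 calls were 1 without crz1 T0 replicate 1, crz1 T0 replicate 2 or WT T0 replicate 2 and 5 without WT T0 replicate 1. No member of a list passed. camera called the tricarboxylic acid, trehalose and amino acid lists higher and cytosolic ribosomal proteins lower, each with an adjusted p = 0.729 with an estimated correlation.

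At pH 8.0 the genes below WT in crz1 included TOH1, MXR2-1 and the calcium pump PMC1. TOH1 stayed at 31.8, 23.2 and 10.7 RPKM in crz1 against 352, 488 and 242 in WT, with log2 differences of -3.46 (adjusted p = 8.36e-10), -4.31 (7.37e-12) and -4.35 (6.22e-12). MXR2-1 differed by -2.23 (6.04e-06) at T15 and -2.71 (1.43e-07) at T30. PMC1 reached 21.7 ± 1.68 RPKM at T15 and 24.01 ± 3.19 at T30 in crz1 (SD, n = 3), a difference from WT of -1.60 (SE 0.28, adjusted p = 0.00379) and -1.54 (0.00712), and did not pass at T60 (-0.48, adjusted p = 0.956). PAS_chr2-1_0009, a neighbour of MXR2-1, was lower at T30 by -1.97 (SE 0.26, adjusted p = 9.58e-05), SKG3 at T15 by -1.66 (SE 0.29, adjusted p = 0.00379) and CZF1 at T60 by -2.45 (SE 0.40, adjusted p = 0.00266). The mannosyltransferase copy MNN2-3 differed by -3.23 (SE 0.61, adjusted p = 0.00715) at T15, -3.79 (0.00149) at T30 and -3.20 (0.0106) at T60. At T15 its call was lost without crz1 T15 replicate 1 (0.0754) or WT T15 replicate 1, and at T60 without crz1 T60 replicate 1 (0.128), crz1 T60 replicate 2 or WT T60 replicate 2. PAS_chr1-4_0696 was lower at T60 (-3.68, SE 0.60, adjusted p = 0.00266). A pseudocount of 0.1 RPKM ended the calls of MNN2-3 at all 3 times and of PAS_chr1-4_0696, and quantile normalization those of SKG3 (0.0865) and of MNN2-3 at T60 (0.122). PHO89, with log2 differences of -0.13, 0.08 and 0.40, and ENA2, with 0.06, -0.06 and 0.08, did not pass.

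In limma 0, 0 and 1 genes were higher and 21, 14 and 10 lower in crz1 than in WT at T15, T30 and T60 by at least 2-fold, with 137, 114 and 117 at an unadjusted p under 0.05. The counts at an unadjusted p lie below a share of 0.05 of the 4226 tested genes. Lower genes numbered 30, 23 and 12 with median-ratio scaling and 29, 21 and 9 with quantile normalization. With library type as a covariate they numbered 31, 30 and 11. FET4-1 was the gene higher at T60 (2.05, adjusted p = 0.0112), a call lost without WT T60 replicate 2 (0.202) or crz1 T60 replicate 1 or 2 and with quantile normalization (0.0993). The count of 21 at T15 was 12 without crz1 T15 replicate 2, 8 without WT T15 replicate 1 and 11 without WT T15 replicate 2. The 14 at T30 were 8 without crz1 T30 replicate 3 or WT T30 replicate 1 and 9 without WT T30 replicate 2, and the 11 at T60 were 5 without crz1 T60 replicate 2 and 6 without WT T60 replicate 2. NRG1 (-3.57 at T15, adjusted p = 0.0274) lost its call without crz1 T15 replicate 1, crz1 T15 replicate 2 (0.252), WT T15 replicate 1 or WT T15 replicate 2 and with quantile normalization (0.0735). BUB3 at T60 (adjusted p = 0.00992), listed at 0 in all 12 crz1 libraries and at 10.3 ± 5.39 RPKM in WT, lost its call without WT T60 replicate 2 (0.121), WT T60 replicate 1 or crz1 T60 replicate 2. The call of NRG1 also ended when the higher-median libraries were left out.

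**Figure D3:**
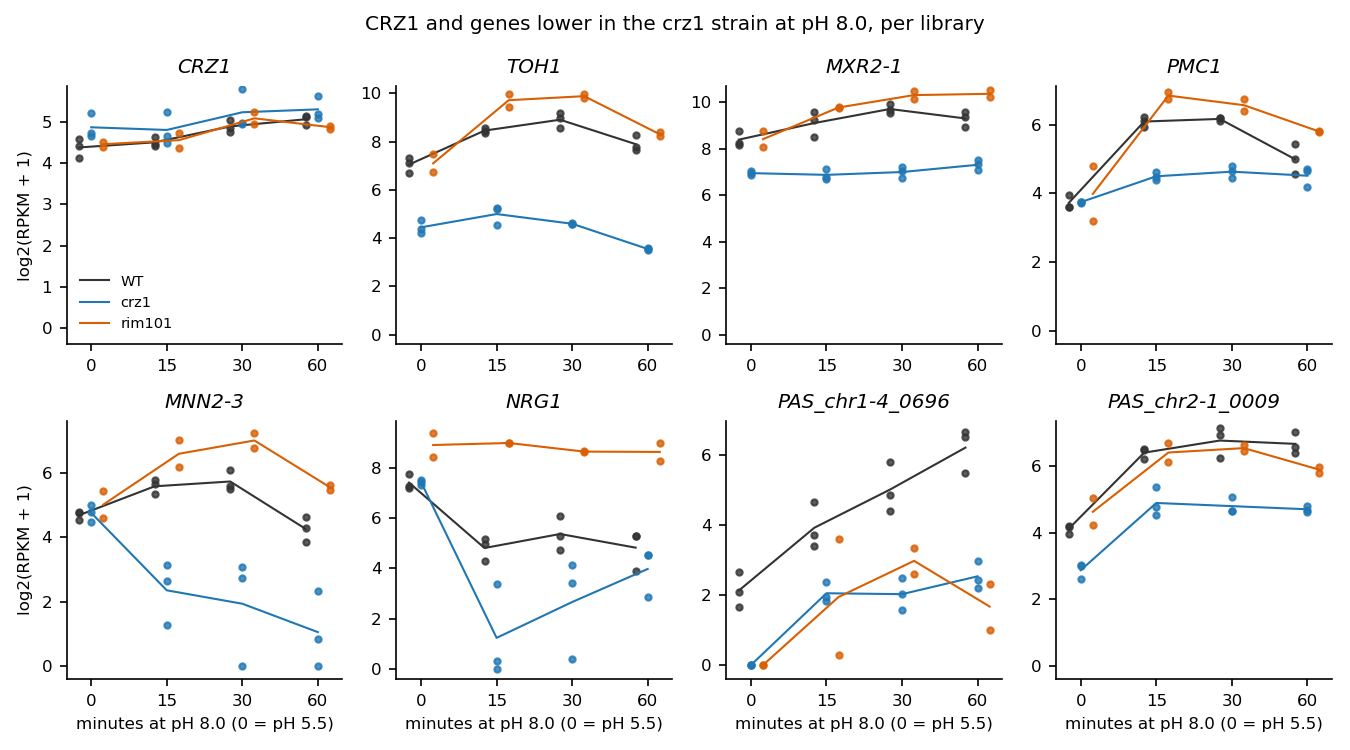
Dots are libraries and lines group means of log2(RPKM + 1) against minutes at pH 8.0 for WT (n = 3), crz1 (n = 3) and rim101 (n = 2). TOH1 lies lower in crz1 than in WT at all 4 times and PMC1 at T15 and T30, while for CRZ1 the strains overlap.

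At T15 and T30 most genes that changed in WT also passed in crz1, and at T60 the share depended on scaling and library type. In limma 487, 522 and 368 genes rose and 256, 166 and 170 fell in crz1 at T15, T30 and T60 at least 2-fold. Median-ratio scaling gave 387 and 263 at T30 and 314 and 244 at T60, and quantile normalization 423 and 387, 305 and 282, and 259 and 254. In crz1 MIT1 rose by log2 changes of 6.73, 6.02 and 5.45 and PHO89 by 4.48, 4.84 and 4.36. Of the WT genes that rose, 332 of 427, 430 of 726 and 306 of 826 also rose at least 2-fold in crz1, and of those that fell, 133 of 149, 98 of 115 and 96 of 141 also fell. At T60 the shared rises were 37.0% of those in WT as deposited and 49.2% with median-ratio scaling. They were 56.4% with quantile normalization and 65.2% with library type as a covariate. The Spearman correlation of the responses of WT and crz1 across genes, which are not independent replicates, was 0.786, 0.841 and 0.787. The crz1 minus WT difference in response passed in limma at 0, 1 and 0 genes, with 77, 75 and 84 at an unadjusted p under 0.05. The 1 gene, PAS_chr1-1_0101 (an arrestin-like protein, named because it is the whole count), was listed at 0 in all 12 crz1 libraries and at 14.2 ± 5.53 RPKM in WT at T30 (adjusted p = 0.00558). The count at T30 was 2 without WT T0 replicate 2 or WT T30 replicate 3, and the count at T60 was 1 without WT T60 replicate 1. PMC1 had a difference in response of -1.62 at T15 (adjusted p = 0.264) and -1.56 at T30 (0.349), and TOH1 of -1.71 at T30 (0.0512), so these did not pass. camera called 9 lists at T15, 1 at T30 and 2 at T60 with no list member passing, each lost with an estimated correlation (adjusted p = 0.0588 for methanol utilisation and peroxisome at T60, higher in crz1, and 0.373 or more for the others).

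The rim101 strain asks the same of Rim101, and at T0 it differed from WT in 5 genes. The siderophore transporter SIT1-1 and PAS_chr4_0077 were listed at 0 in both rim101 libraries (adjusted p = 0.00148 and 4.34e-05), with SIT1-1 at 13.7 ± 8.85 RPKM in WT. PHO89 was at 25.3 ± 1.08 RPKM (SD, n = 2) against 185 ± 103 in WT, a log2 difference of -2.61 (SE 0.52, adjusted p = 0.0457), lost without either rim101 T0 library (0.605 without replicate 2), WT T0 replicate 2 or WT T0 replicate 3. ROP100 was higher by 2.22 (SE 0.37, adjusted p = 0.00459), lost without rim101 T0 replicate 2 (0.162), and TPC1 by 1.44 (adjusted p = 0.0457), lost without rim101 T0 replicate 2 (1.0) or any WT T0 library. PHO89 also lost its call with both other scalings (0.12 and 0.0536), ROP100 and TPC1 with quantile normalization, and all 5 genes with a pseudocount of 5 RPKM. In limma 2 genes were higher and 3 lower, with 167 at an unadjusted p under 0.05. The 5 calls were 3 without rim101 T0 replicate 2 or WT T0 replicate 3 and 8 without WT T0 replicate 1 or 2, and the split was 3 higher and 3 lower with median-ratio scaling and 1 and 8 with quantile normalization. camera called 6 lists (phosphate, respiratory chain, cytosolic ribosomal proteins and proteasome lower, cell wall and ribosome biogenesis higher), each with an adjusted p of 0.570 or more with an estimated correlation.

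At pH 8.0 several of the strongest WT rises were not seen in rim101. PHO89 stayed at 41.8 ± 21.8, 16.5 ± 7.30 and 28.9 ± 0.766 RPKM (SD, n = 2), and its log2 difference from WT was -6.55 (adjusted p = 5.36e-09), -7.95 (1.65e-10) and -6.31 (1.58e-08) at T15, T30 and T60. MIT1, ZRT1 and FET4-1 were listed at 0 in all 8 rim101 libraries, and ZPS1 at T15 and T30. The rim101 minus WT difference in response passed for MIT1 (adjusted p = 1.64e-05, 6.36e-05 and 0.000242), for ZPS1 at T15 and T30 (0.00148 and 0.000267) and for FET4-1 at T15 and T30 (0.00148 and 9.7e-05). ENA2 reached 39.5, 57.7 and 27.4 RPKM in rim101 against 177, 279 and 227 in WT, with log2 differences of -2.15 (1.48e-05), -2.25 (4.5e-06) and -3.01 (5.46e-08). ENA2 still rose in rim101 at T30 by 1.39 (adjusted p = 0.00245), and its difference in response did not pass at T15 (-1.30, adjusted p = 0.312) or T30 (-1.41, 0.137). The aspartyl protease copy YPS1-2 (PAS_chr3_1157) was at 29.6 ± 6.18 RPKM at T30 against 476 ± 42.6 in WT, and its difference in response was -2.34, -3.34 (SE 0.32, adjusted p = 4.46e-07) and -2.20.

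Some of these tests of the difference in response rested on single libraries. For PHO89 it was -3.94 (SE 0.74, adjusted p = 0.00738), -5.34 (9.71e-05) and -3.70 (0.0150). Its call was lost at T15 without rim101 T15 replicate 2 (0.143) or rim101 T0 replicate 1, and at T60 without any of the 4 rim101 libraries compared (0.0980 without rim101 T60 replicate 1). ENA2 at T60 (-2.16, SE 0.38, adjusted p = 0.00385) lost it without rim101 T60 replicate 2 (0.0672). For RIM101 the difference in response was -1.76, -1.76 and -1.93 (adjusted p = 0.0221, 0.0150 and 0.00926). The RIM101 call was lost at T15 without rim101 T15 replicate 2 (0.215), either rim101 T0 library, WT T15 replicate 1 or WT T15 replicate 3, at T30 without rim101 T30 replicate 2 (0.237) or rim101 T0 replicate 2, and at T60 without rim101 T60 replicate 1 (0.107) or rim101 T0 replicate 2. ZRT1 at T15 and T30 (adjusted p = 0.0428 and 0.0342), RLM1 at T30 (0.0356), FET4-1 at T60 (0.0232) and ROP100 at T60 (0.0403) each lost the call in 7 or 8 of the 10 fits with 1 library left out and with both other scalings, with a highest adjusted p without 1 library of 0.216 for ZRT1 without rim101 T15 replicate 2, 0.237 for RLM1 without rim101 T30 replicate 2, 0.141 for FET4-1 without rim101 T60 replicate 1 and 0.233 for ROP100 without rim101 T0 replicate 2. The fits that kept these calls were those without WT T0 replicate 2 or 3 for ZRT1 (at T30 also WT T30 replicate 1), WT T0 replicate 1 or WT T30 replicate 1 for RLM1, WT T0 replicate 1 or 2 or WT T60 replicate 2 for FET4-1, and WT T0 replicate 1 or 3 for ROP100. At T60 both other scalings ended the calls of YPS1-2 (0.176 and 0.131) and RIM101 (0.231 and 0.341), and median-ratio scaling that of PHO89 (0.203).

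**Figure D4:**
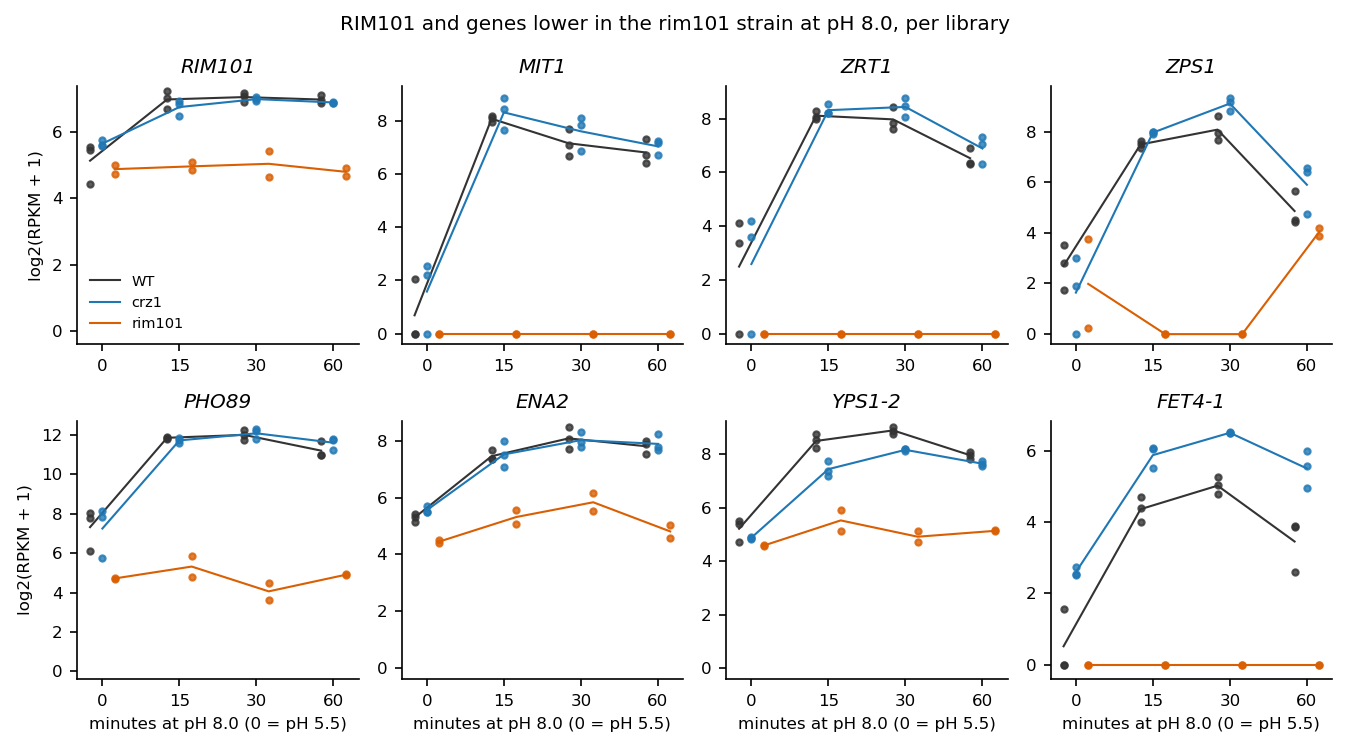
Dots are libraries and lines group means of log2(RPKM + 1) against minutes at pH 8.0 for WT (n = 3), crz1 (n = 3) and rim101 (n = 2). PHO89, ENA2 and YPS1-2 rise in WT and crz1 and lie lower in rim101 at pH 8.0, where ENA2 also rises at T30 as deposited. MIT1, ZRT1 and FET4-1 are listed at 0 in all 8 rim101 libraries.

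Other phosphate and metal genes had a positive difference in response. Some rose more in rim101, and others fell in WT only or fell less in rim101. The phosphate transporter copy PHO84-1 (PAS_chr4_0337) went from 32.5 ± 12.1 RPKM to 1998 ± 636, 3668 ± 430 and 1199 ± 256 RPKM in rim101 (SD, n = 2), while WT went from 75.5 to 68.5, 30.7 and 6.40 RPKM, a difference in response of 6.13, 8.06 and 9.21 (SE 1.00, adjusted p = 0.00148, 2.93e-05 and 4.51e-06). PHO84-2, which fell in WT, was at 469 ± 83.5 RPKM at T15 in rim101 and 7.28 ± 1.42 in WT (difference in response 5.48, SE 0.54, adjusted p = 9.95e-07). Its change in rim101 at T30 was -0.64. FRE3 (PAS_chr4_0240), a ferric reductase, was listed at 0 in all 12 WT and all 12 crz1 libraries and reached 391 ± 77.7 RPKM at T30 in rim101 (adjusted p = 3.44e-08, 8.41e-11 and 4.07e-09). The reductase copy FRE2-1 was listed at 0 in WT up to T30 and reached 128 ± 27.4 RPKM at T30 in rim101 (adjusted p = 9.15e-06). The iron permease FTR1 reached 877 ± 74.3 RPKM at T30 (4.03, SE 0.94, adjusted p = 0.0363) and the acid phosphatase PHO5 333 ± 45.4 RPKM (2.36, SE 0.48, adjusted p = 0.0113). FTR1 lost its call in 8 of 10 fits with 1 library left out (0.243 without rim101 T0 replicate 1, all but those without WT T0 replicate 1 or WT T30 replicate 1), PHO84-1 at T15 with a pseudocount of 0.1 RPKM, and PHO5 without rim101 T0 replicate 1 (0.0982) or rim101 T30 replicate 1. The ferroxidase FET3 (3.63 at T30, adjusted p = 0.00048) and the zinc transporter ZRT2 (1.45 at T15, adjusted p = 0.00459) are list members outside the naming rule, chosen after their values were seen. At pH 8.0 rim101 also held NRG1 above WT at T15 and T60 (4.17 and 3.80) and the sodium antiporter NHA1 at T30 and T60 (3.84 and 3.39).

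**Figure D5:**
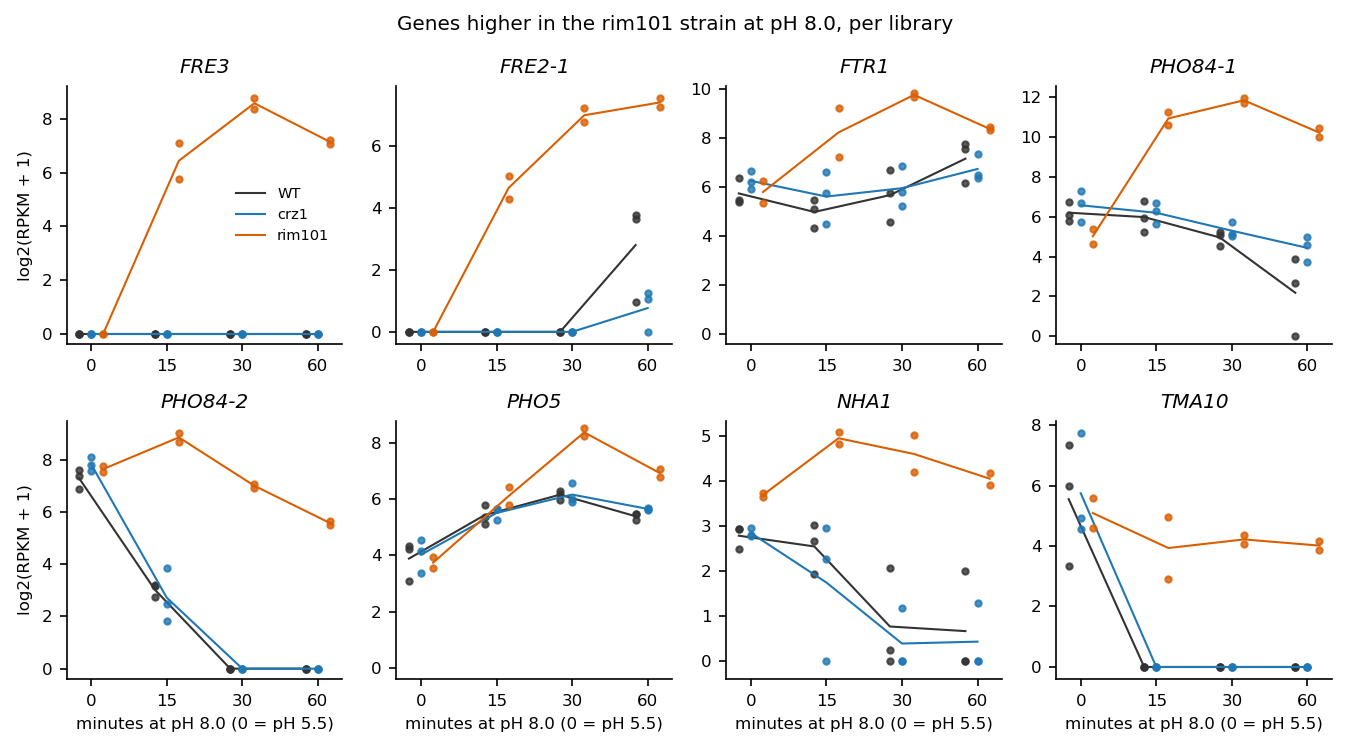
Dots are libraries and lines group means of log2(RPKM + 1) against minutes at pH 8.0 for WT (n = 3), crz1 (n = 3) and rim101 (n = 2). PHO84-1, FRE3 and FRE2-1 rise in rim101 after T0, where FRE3 is listed at 0 in all WT and crz1 libraries.

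In limma the rim101 minus WT difference in response was positive for 10, 19 and 15 genes and negative for 9, 14 and 9 at T15, T30 and T60 at least 2-fold (117, 162 and 312 at an unadjusted p under 0.05), and at T60 it was 11 and 2 with median-ratio scaling and 13 and 3 with quantile normalization. The 19 at T15 were 12 without rim101 T0 replicate 1 and 11 without rim101 T15 replicate 2, and the 33 at T30 were 21 without rim101 T30 replicate 1. At T60 the 24 were 15 without rim101 T0 replicate 1 or WT T60 replicate 2, 10 without rim101 T60 replicate 1, 12 without rim101 T60 replicate 2 and 14 without WT T60 replicate 1. Compared with WT directly, 27, 27 and 33 genes were higher and 17, 37 and 32 lower in rim101 (272, 374 and 542 at an unadjusted p under 0.05), with 19 and 23 at T15 by median-ratio scaling and 21 and 23 by quantile normalization. The 65 genes at T60 were 34 without rim101 T60 replicate 1, 41 without rim101 T60 replicate 2 and 170 without WT T60 replicate 3. Of 23 metal uptake genes 2, 4 and 3 had a positive and 1, 1 and 0 a negative difference in response (4, 4 and 4 positive and 1, 2 and 1 negative when adjusted over the list alone), and camera called the list higher at T60 (adjusted p = 0.000189, against an adjusted p = 0.0517 with an estimated correlation, fry directional adjusted p = 0.0405). Of 12 phosphate genes 0, 1 and 0 had a positive and 1 a negative difference at each time (0, 2 and 1 positive and 1, 2 and 2 negative when adjusted over the list alone), the negative one PHO89, since the PHO84 copies match no list name. At T60 camera also called ribosome biogenesis (median -1.55, adjusted p = 3.16e-09) and the mitochondrial ribosome (-1.04, adjusted p = 0.000229) lower and methanol utilisation and peroxisome higher (adjusted p = 0.0107), with no called member in the ribosome lists and an adjusted p = 0.908, 0.916 and 0.0517 with an estimated correlation. The median of the mitochondrial ribosome relative to all genes turned from -0.57 to 0.03 without the higher-median libraries, where WT T60 keeps 1.

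In rim101 itself 197, 840 and 88 genes rose and 91, 158 and 41 fell at T15, T30 and T60 at least 2-fold, and with them HSP12 (log2 change 4.97 at T15), MSC1 (6.87 at T15) and VTC2 (3.79 at T30), which also rose in WT. Median-ratio scaling gave 320 and 301 at T30 and 81 and 61 at T60, and quantile normalization 145 and 134, 240 and 347, and 69 and 62. Both rim101 T30 libraries are of the higher-median type. The 288 genes at T15 were 129 without rim101 T0 replicate 1 and 128 without rim101 T15 replicate 2. The 998 at T30 were 252 and 563 without rim101 T0 replicate 1 and 2, and 217 and 425 without rim101 T30 replicate 1 and 2. The 129 at T60 were 47 without rim101 T0 replicate 1, 43 without rim101 T60 replicate 1 and 65 without rim101 T60 replicate 2. Of the WT genes that rose, 148 of 427, 438 of 726 and 67 of 826 also rose in rim101. A called smaller response was seen in 9, 11 and 9 of them and a called larger one in 2, 3 and 2. Of those that fell in WT, 68 of 149, 73 of 115 and 27 of 141 also fell in rim101, and 1, 7 and 9 had a called smaller fall. At T15 the shared rises were 34.7% of those in WT as deposited, 28.5% with median-ratio scaling and 25.2% with quantile normalization. They were 30.5% with library type as a covariate. At T30 they were 60.3% of those in WT as deposited, 41.1% with median-ratio scaling, 40.8% with quantile normalization and 25.8% with library type as a covariate. At T60 they were 8.11%, 10.3%, 12.4% and 24.7%. The Spearman correlation of the responses of WT and rim101 across genes was 0.650, 0.753 and 0.481.

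The responses of the mutants were also compared with each other. Taken as crz1 minus rim101, the difference in response at T30 was 5.50 (SE 0.74, adjusted p = 6.13e-05) for PHO89, 2.95 (SE 0.32, adjusted p = 3.5e-06) for YPS1-2, -8.10 (SE 1.00, adjusted p = 1.95e-05) for PHO84-1 and -3.65 (adjusted p = 0.000403) for FET3. PMC1 rose less in crz1 than in rim101 at T15 (-2.11, SE 0.44, adjusted p = 0.0131), and TOH1 differed by -2.07, -2.64 (adjusted p = 8.3e-05) and -2.10. In limma 11, 20 and 8 genes were positive and 30, 32 and 16 negative at least 2-fold (193, 279 and 140 at an unadjusted p under 0.05), and at T60 quantile normalization gave 4 and 15. The 41 at T15 were 23 without rim101 T0 replicate 1 and 12 without rim101 T15 replicate 2. The 52 at T30 were 33 without rim101 T0 replicate 1 and 28 without rim101 T30 replicate 1. The 24 at T60 were 15 without crz1 T60 replicate 2, 14 without rim101 T0 replicate 1 or rim101 T60 replicate 2 and 13 without rim101 T60 replicate 1.

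Both mutants were compared with the same WT libraries, which links the comparisons. No gene passed in the difference in response of both mutants at the same time. In the direct comparisons YPS1-2 was lower in both at T15 (independent lists would share 0.0845 genes) and PAS_chr1-4_0696 in both at T60 (0.0757). The 100 simulations of unchanged mutants against the real WT libraries called too few genes to bound these counts. Across genes, the Pearson correlation of the difference in response in crz1 with that in rim101 was 0.414, 0.0241 and 0.647 at T15, T30 and T60, against 0.447, 0.446 and 0.445 in the simulations from the shared controls alone. The covariance was 0.245, 0.0145 and 0.497 against 0.384, 0.385 and 0.381. At T60 the direct differences from WT had a correlation of 0.629 (simulated 0.446) and a covariance of 0.389 (simulated 0.191). At T60, 2 of 3 WT, 1 of 3 crz1 and 0 of 2 rim101 libraries are of the higher-median type, which the simulations leave out, so library type is not separated from a shared effect of the mutants.

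The authors' deposited table compares each group with WT T0. At an FDR under 0.05 and at least 2-fold, the authors' deposited table has 217, 164 and 85 genes rising and 151, 165 and 132 falling in WT at T15, T30 and T60, and 691 rising and 634 falling in rim101 at T30. Its log2 fold changes had a Spearman correlation across genes of 0.922 to 0.968 with the differences of mean log2(RPKM + 1) computed here over its 11 comparisons. With crz1 and rim101 at T0 the authors' deposited table has 3 and 2 genes.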

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

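All 4 tests that weigh explanations in this part were chosen only after the result was seen, whereas the counts of other splits were planned, except for the splits within same-numbered pairs. Each gene or count below stands here because a test of the difference in response itself (limma, adjusted p under 0.05) separated 2 strains.

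The rim101 minus WT difference in response passed for 19 genes at T15, 33 at T30 and 24 at T60. The difference in response between crz1 and rim101 passed for 41, 52 and 24 genes, and the crz1 minus WT difference for 1 gene at T30. Negative differences from WT in rim101 were those of PHO89 (log2 difference -5.34 at T30), YPS1-2 (-3.34 at T30), ENA2 (-2.16 at T60), RIM101 (-1.93 at T60), ROP100 (-2.30 at T60) and RLM1 (-1.55 at T30). The call of ENA2 was lost without rim101 T60 replicate 2 (adjusted p = 0.0672), and that of RIM101 without rim101 T60 replicate 1 (0.107) or rim101 T0 replicate 2. ROP100 and RLM1 each lost theirs in 8 of 10 fits without 1 library (highest adjusted p = 0.233 without rim101 T0 replicate 2 and 0.237 without rim101 T30 replicate 2), as did ZRT1 at T15 (0.216 without rim101 T15 replicate 2). MIT1 (adjusted p = 1.64e-05 at T15), ZRT1 (0.0428 at T15), ZPS1 (0.000267 at T30) and FET4-1 (9.7e-05 at T30) were listed at 0 in rim101 at these times, so no fold is given. Positive differences were those of PHO84-1 (9.21 at T60), FTR1 (4.03 at T30) and PHO5 (2.36 at T30). PHO84-2 (adjusted p = 2.13e-08), FRE2-1 (9.15e-06) and FRE3 (8.41e-11) were listed at 0 in WT at T30.

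Of 44 measured genes of phosphate and metal uptake, numbered copies included, 9 had a positive rim101 minus WT difference in response: PHO84-1, PHO84-2, PHO5, FRE3, FRE2-1, FTR1, FET3, ZRT2 and FEP1. FEP1 is here by its symbol, and the file describes it as an activator of nitrogen-regulated genes, so a regulator and no transporter. For PHO84-2 and FEP1 this is a smaller fall, with changes of -0.64 at T30 and -2.28 at T60 in rim101. ZRT2 changed by 0.50 at T30 in rim101. Library composition would end these calls once it is in the model, and 100% of the 9 kept their call with the share of reads in the 5 top genes as a covariate, which argues against it as the whole cause. With library type as a covariate 88.9% kept it. For those 8 this argues against a type effect shared by all strains as the whole cause. Both rim101 T30 libraries are of the higher-median type, so an effect specific to them was not tested. FEP1 lost its call, with a log2 difference of 3.36 (SE 0.78) before and 3.00 (SE 0.71, adjusted p = 0.0526) after, a smaller difference over a similar spread. Reads moving between the copies of PHO84 would cancel in their sum. The summed difference was 94.6% of that of the single copies (median of PHO84-2 at T30 and PHO84-1 at T60), so the difference holds for the copies together. PHO84-1 outweighs PHO84-2 in the sum (mean 471 against 90.5 RPKM), so the sum cannot tell whether reads of PHO84-1 were counted for PHO84-2. That 1 library made the differences is argued against, since each of the 9 genes kept at least 86.4% of its difference without any single library. The calls of PHO84-1, PHO84-2, FRE3, FRE2-1, FET3 and ZRT2 stayed in each of these fits. FTR1 and FEP1 lost theirs in 8 of 10 (highest adjusted p = 0.243 and 0.419) and PHO5 in 2 (0.0982). Their lowest log2 differences in these fits were 3.49 (SE 0.93), 2.99 (SE 0.79) and 2.14 (SE 0.49), against 4.03 (SE 0.94), 3.36 (SE 0.78) and 2.36 (SE 0.48) with all libraries, so these calls lie near the threshold. A candidate explanation from the design is that cells of the rim101 strain, with PHO89, ZRT1 and FET4-1 low or listed at 0, bring up other phosphate and metal genes or keep them from falling, which was not tested.

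For the crz1 minus WT difference in response at T30, chance cannot be excluded: of 100 splits drawn from the 200 possible splits of the same libraries, 17 gave at least as many genes as the real 1 (highest other 12). Since the numbers may pair crz1 and WT at T0 and at T30, the 32 splits that exchange libraries only within a same-numbered pair were also run, and 8 of them were as large (highest other 10). All other possible splits part fewer pairs. At T15 and T60 the real count was 0, which all 100 splits reach by construction, so the splits decide nothing there. The highest of the drawn other splits had 401 genes at T15 and 1529 at T60. Among the 32 splits within same-numbered pairs the highest had 419 genes at T15 and 9 at T60. Splits that call so many genes point to a structure of the samples. The T15 split with 401 genes exchanged WT T0 replicate 2 and WT T15 replicates 1 and 2 with crz1 libraries.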

How the results depend on the processing

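Tests chosen only after the results were seen are those with the read share or library type as a covariate, without the 9 higher-median libraries, without genes listed at 0 in a compared library, with numbered copies in the lists, and the splits that part all same-numbered pairs. Counts are of genes changed at least 2-fold and "difference" stands for difference in response. Of the 218 values of named genes, 194 kept their direction and their side of the threshold with median-ratio scaling, 179 with quantile normalization, 203 with either pseudocount, 213 with no filter, 204 of 206 with a mean of at least 10 RPKM, 214 with array weights, 215 with the replicate block, all but 16 with the read share and 205 with library type as a covariate, 111 with the compared groups only and 146 of 193 without the higher-median libraries. Of the refits of named genes without 1 library, 1199 did and 228 did not. No minimum fold, fry and numbered copies in the lists moved no count by over 1.5 times, and leaving out the higher-median libraries gives no value for rim101 at T30. Where a value below moved, the cause was not tested. Fits of fewer libraries or genes can have less to call, but some called more. For rim101 at T30 the count rose from 998 to 1721 with the compared groups only. For WT at T60 it rose from 967 to 1681 without WT T60 replicate 3. By the labels the libraries share only a number. Residual correlations over all strains and times exceeded 0.1 in 33 of 48 pairs of the same strain and number and in 15 of 28 of the same time and number. They ran from -0.526 to 0.877 and from -0.777 to 0.903, and 22 of 32 libraries were closest to their own number, a hint from the data and not the design. Depth limits low genes, and of 2-fold changes 4.63% were recovered in the simulated rim101 minus WT difference at T30.

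With the compared groups only, the counts against T0 were 234, 218 and 95 in WT at T15, T30 and T60, 0, 1721 and 52 in rim101, and 349 in crz1 at T60. They were 0, 2, 2 and 1 for crz1 vs WT at T0, T15, T30 and T60, 11, 31 and 24 for rim101 vs WT at T15, T30 and T60, 5, 15 and 7 for the rim101 minus WT difference and 4 for the difference between crz1 and rim101 at T15.

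With array weights, whose fit did not converge, counts against T0 were 1194, 1575 and 2319 in WT, 1251, 1125 and 951 in crz1, and 2060 and 397 in rim101 at T30 and T60. They were 353, 931, 345 and 1462 for crz1 vs WT and 110, 1245 and 1649 for rim101 vs WT at T0, T30 and T60. The differences were 495, 670 and 1914 for crz1 minus WT, 467 and 1793 for rim101 minus WT at T30 and T60, and 1252 and 109 between crz1 and rim101 at T30 and T60, and the overlap of crz1-dependent and rim101-dependent genes was 1590.

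With the share of reads in the 5 top genes as a covariate, counts were 872 and 614 for WT at T15 and T60, 352 and 307 for rim101 at T30 and T60, 5, 36, 34 and 17 for crz1 vs WT and 13 for rim101 vs WT at T0. The differences were 3, 2 and 1 for crz1 minus WT, and 30 for rim101 minus WT and 75 between crz1 and rim101 at T15. With library type as a covariate they were 369 and 264 for rim101 at T30 and T60, 10 for rim101 vs WT at T0, 30 for crz1 vs WT at T30, 5, 7 and 1 for the crz1 minus WT difference and 63 for the difference between crz1 and rim101 at T15. Without the higher-median libraries they were 254 for WT and 219 for rim101 at T60, 1 for crz1 vs WT and 10 for rim101 vs WT at T0, and 2 and 3 for the crz1 minus WT difference at T30 and T60. The median of the mitochondrial ribosome in the rim101 minus WT difference at T60, relative to all genes, then turned to 0.0325.

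Without genes listed at 0 in a compared library, counts were 375 and 556 for WT at T15 and T30, 492 and 351 for crz1 at T15 and T60, 0, 21, 31 and 30 for rim101 vs WT, 8 for crz1 vs WT at T30, 8, 11 and 6 for the rim101 minus WT difference, 0 for the crz1 minus WT difference at T30 and 16, 20 and 6 for the difference between crz1 and rim101.

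With quantile normalization, counts were 496 and 533 for WT at T30 and T60, 587 for rim101 at T30, 9 for rim101 vs WT at T0 and 2 for the crz1 minus WT difference at T30. CRZ1 in WT at T60 turned to -0.13, and relative to all genes the median of cytosolic ribosomal proteins turned to 0.0881 in WT at T30. The list median, cytosolic ribosomal proteins, rim101 minus WT difference in response at T60, turned to -0.0134. With median-ratio scaling, counts were 621 for rim101 at T30, 23 for crz1 vs WT at T30, 1 and 2 for the crz1 minus WT difference at T15 and T30 and 13 for the rim101 minus WT difference at T60. With replicate number as a block they were 1650 for rim101 at T30 and 1, 3 and 1 for the crz1 minus WT difference. In the 3 comparisons that the numbers may pair, the block gave 837 for crz1 at T15 and 4 and 21 for crz1 vs WT at T0 and T30, and changed no call of a named gene.

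A pseudocount of 0.1 RPKM gave 5 for crz1 vs WT and 11 for rim101 vs WT at T0 and 2 for the crz1 minus WT difference at T60, and one of 5 RPKM 0 for rim101 vs WT at T0 and 3 for the crz1 minus WT difference at T30. A mean of at least 10 RPKM gave 41 for rim101 vs WT and 13 for the rim101 minus WT difference at T60 and 0 for the crz1 minus WT difference at T30. No filter gave 1 and 4 for the crz1 minus WT difference at T15 and T30. camera called 66 lists over 11 comparisons, 0 with an estimated correlation, and fry 45.

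Leaving out 1 library in turn, counts ran from 509 (without WT T30 replicate 1) to 1033 for WT T30 vs T0, from 463 (without WT T60 replicate 1) to 1681 (without WT T60 replicate 3) at T60, and from 128 to 304, 217 to 563 and 43 to 127 for rim101 at T15, T30 and T60. They ran from 1 to 5, 8 to 28, 8 to 15 and 5 to 15 for crz1 vs WT, from 3 to 8 at T0 and 34 to 170 at T60 for rim101 vs WT, from 11 to 26, 21 to 38 and 10 to 33 for the rim101 minus WT difference, from 1 to 2 at T30 and 0 to 1 at T60 for the crz1 minus WT difference, and from 12 to 44, 28 to 51 and 13 to 20 for the difference between crz1 and rim101. The report names the libraries behind each.

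With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Of the real and the highest other split, counts were 576 and 13, 841 and 0, and 967 and 926 for WT at T15, T30 and T60, and 743, 688 and 538 against 0 for crz1. For crz1 vs WT they were 3 and 62, 21 and 61, 14 and 14, and 11 and 1331 at T0, T15, T30 and T60, where 3, 2, 2 and 2 splits were as large as the real one. In the 3 comparisons that the numbers may pair, 4 splits part all 3 pairs, and the highest other of these had 0 genes for crz1 at T15 and 1 and 0 for crz1 vs WT at T0 and T30. The 62 and 14 come from splits that keep 2 same-numbered libraries together. The splits with 926 and 1331 genes follow library type, as they put the higher-median libraries of T60 together. With library type as a covariate the real count for WT at T60 was 650, and 509 of the 967 calls were kept. The real count for crz1 vs WT at T60 was 12, and all 11 calls were kept.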

Other observations

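Tests chosen only after the result was seen are those of gene length, replicate number and exposure to pH 8.0 for the library types and of low values set to 0 for the zeros.

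Further lists moved in part in WT, and several depended on scaling. Of 20 cell cycle and histone genes 6, 7 and 8 rose and 0 fell at T15, T30 and T60 (7, 9 and 8 when adjusted over the list alone), such as MCM6 (log2 change 2.29 at T30, not passed with quantile normalization, adjusted p = 0.0825), with 5, 4 and 2 rising under median-ratio scaling, 2, 2 and 3 under quantile normalization and 10, 11 and 6 with library type as a covariate. Of 15 vacuolar ATPase genes 0, 2 and 5 rose and 1, 0 and 0 fell (0, 1 and 5 rose and 1, 0 and 0 fell when adjusted over the list alone), among them STV1 (1.23 at T60, adjusted p = 0.000518, and 0.337 with quantile normalization), against 1 rising and 2 falling at T60 with median-ratio scaling. Of 30 proteasome genes 4 fell at T15 and 1 and 3 rose at T30 and T60 (3, 0 and 0 when adjusted over the list alone), with PRE6 at -0.70 at T15 (adjusted p = 0.00104). At T15 17 of them fell with median-ratio scaling, 10 with quantile normalization and 13 with library type as a covariate, and at T30 median-ratio scaling gave 0 rising and 5 falling. The camera call of the proteasome at T15 (adjusted p = 1.92e-06, lower) had an adjusted p = 0.526 with an estimated correlation, and at T60 the median-ratio scaling gave 0 rising and 2 falling. Of 20 ergosterol genes 1, 4 and 3 rose and 1, 0 and 2 fell (1, 4 and 1 rose and 1, 0 and 0 fell when adjusted over the list alone), such as ERG4 (1.17 at T30), against 1 rising and 7 falling at T30 and 0 and 6 at T60 with median-ratio scaling. Of 19 genes of nitrogen source and amino acid transport 4, 3 and 3 rose and 3, 2 and 3 fell (5, 3 and 5 rose and 3, 2 and 4 fell when adjusted over the list alone), against 1 rising and 5 falling at T30 and at T60 with median-ratio scaling and 1 and 4, then 1 and 5 with quantile normalization. Among them were the vacuolar transporter AVT3, up by 3.79 at T30, and the ammonium permease MEP1, at -4.05 at T15. camera called the list at T30 (adjusted p = 0.0224, lower, against an adjusted p = 0.14 with an estimated correlation). None of 4 hexose transport genes passed as deposited, and 1 fell at T60 with either other scaling. Of 7 mating and sporulation genes, the markers of another cell state, 0, 1 and 1 rose (0, 0 and 1 when adjusted over the list alone), and 0 with either scaling. In the rim101 minus WT difference in response camera called the proteasome higher at T15 and T30 (adjusted p = 0.000103 and 0.00198, against an adjusted p = 0.81 and 0.96 with an estimated correlation) with no member passing.

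Some genes were listed at 0 in every library of 1 strain while another strain averaged at least 10 RPKM at pH 8.0. In rim101 there were 7 such genes: MIT1, ZRT1, FET4-1, PAS_chr1-1_0085 (a MARVEL domain protein), PAS_chr1-1_0210, PAS_chr2-1_0189 and PAS_chr3_0032. WT had 4, FRE3, YOR1-1 (an ABC transporter of the plasma membrane), PAS_chr1-4_0410 and PAS_chr2-1_0270, and all 4 were listed at 0 in crz1 as well and above 0 in rim101. PAS_chr2-1_0270, annotated in protoporphyrin uptake and heme efflux, averaged 107 RPKM in rim101 at pH 8.0. In crz1 there were 6, the same 4 with BUB3 and PAS_chr1-1_0101. These genes were chosen after their values were seen.

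The 2 library types may come from several sources. A few abundant genes taking more reads would leave little of the first within-group component after median-ratio scaling, but it still held 59.3% of the variance within groups (64.6% as deposited), which argues against read share as the whole cause. Gene length does not go with it in the way a length bias needs, with a Spearman rho of -0.209 across genes. Of the 9 libraries 6 carry replicate number 1, and a shared batch of that number stays open (one-sided permutation p = 0.0871). None of the 8 libraries at T0 is among the 9 (one-sided Fisher exact p = 0.0466), so a response to pH 8.0 or resuspension that varies between cultures is a hypothesis that remains, and GC content was not analysed here.

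Zeros were more frequent than sampling allows. At 10 or more reads expected from the other replicates, 5521 of 127089 gene and library pairs (4.34%) were listed at 0, where Poisson sampling gives 0.0185, which argues against sampling. At 2 to 4 expected reads there were 12.3 zeros for each value of 1 to 3 reads (515 against 42), where Poisson sampling gives 0.101, so low values may have been set to 0 before the table was made. A background subtracted per base would make zeros more frequent in long genes, and at 5 to 20 expected reads in 3 classes of gene length the longest had 48.3% zeros and the shortest 30.0%, a ratio of 1.61 that leaves this open. No biological explanation was tested. A gene listed at 0 here, such as ZRT1 in rim101, was therefore not detected in the file, and a low level below such a limit is not excluded.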
